A study of Arabidopsis thaliana with 4 samples.

How the data were processed

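The 4 libraries were made from total RNA of 7-day-old Col-0 seedlings with a stranded mRNA kit, 2 from seedlings labelled as cml39 mutant and 2 from seedlings labelled as wild type. Per the labels the authors used CASAVA 1.8, FastQC, STAR 2.5.2b and DESeq2 1.14.1 with the TAIR10 build; the labels give neither the role of each tool nor the strand setting and gene annotation of the counting, so reads of overlapping genes on opposite strands may have been assigned to either. The deposited table of gene counts holds raw read counts, checked as whole numbers, for these 4 libraries. In the authors' deposited DESeq2 table the signal column is the mean normalized count over the libraries of their fit. That mean is not the mean of the 4 libraries analysed here. The log2 fold change of cml39 over wild type and its standard error in that deposited table are on the log2 scale. The deposited score is the Wald statistic, the log2 fold change over its standard error. The p-value and adjusted p-value are those of the authors, and the adjusted p is absent for 3254 genes.

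Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Low-count genes were removed with filterByExpr, libraries were scaled by the trimmed mean of M values (factors 1.11, 1.08, 0.905 and 0.923 for wt 1, wt 2, cml39 1 and cml39 2), and cml39 was compared with wt by edgeR's quasi-likelihood F test, two-sided. Adjusted p-values are Benjamini-Hochberg values over all 19834 tested genes, with a threshold of 0.05. The biological coefficient of variation was 0.129. Log2 fold changes are given with a standard error, the absolute log2 fold change over the square root of F, and CPM with the SD of the 2 libraries of a group. Where all libraries of a group had 0 counts, the fold was computed against 3 counts over the group, and where a group held 1 to 3 counts the ratio of the summed counts is given with an exact binomial 95% interval. Two-sided exact Poisson 95% intervals are given for the counts of CML39 in the cml39 libraries. Sequenced fragments carry no molecular identifiers, so intervals and floors cover counting error only.

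Before the data were examined, the comparison, its tests, the alternatives, the rule for naming genes and 22 gene lists (387 genes, 315 tested, 7 in more than 1 list) were fixed. Lists with at least 3 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists. The rule named CML39; the 12 genes with the largest rise and the 12 with the largest fall in fitted log2 fold change among those that passed, did not overlap between groups and had a mean of at least 1 CPM; up to 4 members of each list by lowest p; the genes on either side of CML39; and up to 5 genes called in only 1 of this fit and the authors' table. Genes within 1 Mb of CML39 were compared with the rest by Fisher's exact test. Gene symbols and positions come from the reference assembly TAIR10.1, whose gene identifiers matched 32548 of the genes in the count table and not 285. Positions are those of that reference, 1-based, and no coordinates of the authors were used.

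The steps were tested on simulated data with the depth and dispersion of these libraries. Among 19834 simulated genes, 60 of 100 with a log2 change of 1 and 97 of 100 with a log2 change of 2 were recovered, with 13 false calls and 0 calls of the wrong sign, and 0 of 20 lists of unchanged genes were called. Genes were simulated independently of one another, so false calls of lists whose genes are correlated were not tested. Nor was the scaling tested where as many genes change as in these data (40.9%). Alternatives were DESeq2 size factors, upper quartile scaling, all genes with a count, at least 1 CPM in 2 libraries, a robust fit, the replicate number as a block, DESeq2, limma-voom, camera on voom values, an estimated correlation, fry, genes in 1 list only, and each library left out in turn. The adjusted p of an alternative, or its log2 change alone for some left-out libraries, is given beside a gene or list where it crossed the threshold. In the other alternatives that gene or list kept its side, apart from the block, the estimated correlation and fry, which are described together. Comparisons of gene families, also under other scalings, of glucosinolate branches and of seed storage counts were added after the results were seen. Libraries of the authors' fit beyond these 4 were not analysed here.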

Results

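RNA was measured by strand-specific mRNA sequencing in whole 7-day-old Arabidopsis thaliana Col-0 seedlings. The design has 1 comparison, seedlings labelled cml39, a mutant of the calmodulin-like calcium sensor CML39, against wild type (wt), with 2 libraries in each group and 4 in all. The title of the series places CML39 in seed development, germination and fruit development. Libraries held 24101882 counts (wt 1), 19331639 (wt 2), 21981123 (cml39 1) and 19821451 (cml39 2). A gene with 0 counts could have been present at up to 0.113, 0.143, 0.151 and 0.164 CPM, the normalised read count, in these libraries, at 3 counts each. Of 32833 genes in the count table, 24014 had a count and 19834 were expressed enough to be tested. Across genes, log2 CPM correlated at r = 0.992 between the wt libraries and 0.989 between the cml39 libraries, against 0.917 to 0.939 between groups; genes are not independent replicates. The first principal component, which separated the groups, held 89.4% of the variance.

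CML39 (AT1G76640) was read in the libraries labelled cml39 and not in those labelled wt. It had 0 counts in wt 1 and in wt 2, 45 counts in cml39 1 (exact Poisson 95% interval 32.8 to 60.2) and 21 in cml39 2 (13.0 to 32.1). The level was 2.26 and 1.15 CPM in the cml39 libraries and, with 3 counts over the wt group as the floor, at most 0.0631 CPM in wt, so it was at least 27.4-fold higher under the mutant label (adjusted p = 0.00218, n = 2 libraries per group). That limit was 12.1-fold without wt 1, 15.4-fold without wt 2 and 18.22-fold without cml39 1. This goes against a loss of CML39 transcript in the libraries labelled cml39, and every direction given here is that of the libraries labelled cml39 over those labelled wt. In the authors' deposited table CML39 was higher in cml39, by 2.78 ± 0.60 on the log2 scale (SE, adjusted p = 0.000112). Fold changes there come from another estimator, so the sizes are not comparable. The gene has 1 exon on the minus strand of chromosome 1, from 28765254 to 28765866 in TAIR10.1, with the coding sequence from 28765324 to 28765803. CML38 (AT1G76650), another calmodulin-like gene, ends 883 bases upstream on the same strand, from 28766750 to 28768138. It rose by 4.87 ± 0.32 on the log2 scale (SE, adjusted p = 7.92e-05), from 2.67 ± 0.05 CPM (SD, n = 2) to 78.0 ± 32.6. The gene on the other side, AT1G76630, had a log2 difference of 0.24 ± 0.13, which did not pass the test (adjusted p = 0.161).

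**Figure D1:**
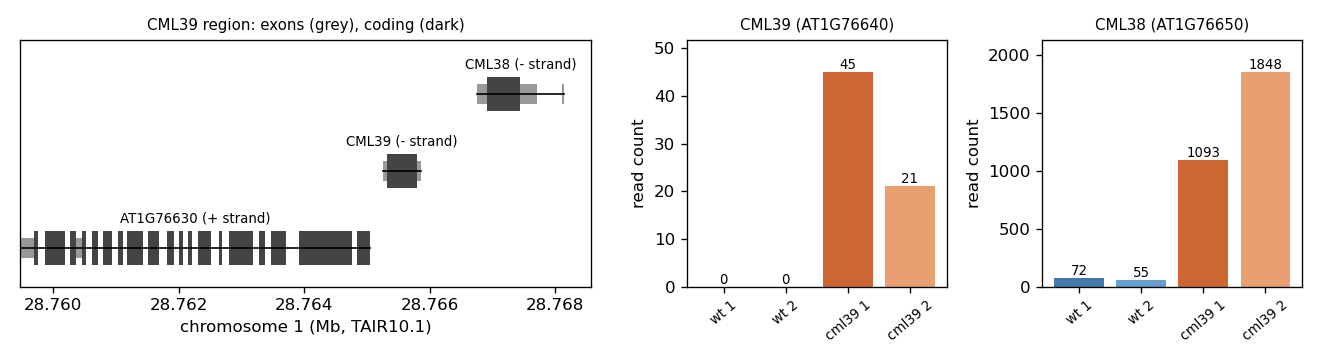
Map of the CML39 region of chromosome 1 (position in Mb, TAIR10.1; grey, exons; dark, coding sequence) and bars of the read counts of CML39 and of CML38 in each library. CML39 had 0, 0, 45 and 21 counts and CML38 72, 55, 1093 and 1848 counts in wt 1, wt 2, cml39 1 and cml39 2.

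Among all tested genes, 8107 changed (40.9%), of which 3822 were higher and 4285 lower in the libraries labelled cml39. At least 2-fold changes numbered 4105, with 1303 higher and 2802 lower. Without wt 1, 4177 genes passed (1997 higher, 2180 lower, 2719 at least 2-fold), and 4163 of them were among the 8107. Upper quartile scaling moved the median log2 change of all genes by -0.148 and gave 2704 higher and 5403 lower, so that the balance of rises and falls rests on the scaling. Values here are relative to the trimmed mean of each library, around which the median log2 change was -0.0052. Nothing in the labels says that the 2 samples of a group were grown or collected apart, so every p-value measures the spread between these samples alone.

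Among the 12 largest rises of the naming rule, CML38 included, that of AT5G24820 was the largest, by 6.36 ± 0.48 on the log2 scale (SE, n = 2, with 1 and 5 counts in wt, 247 and 171 in cml39). AT1G33760 was 77.3-fold higher, with a counting interval of 26.0 to 378 since wt held 3 counts (34.0-fold without wt 1, at least 43.3-fold without wt 2). The zinc finger genes ZAT7 (5.99 ± 0.92; 83 and 377 counts in cml39) and AT3G46080 (5.93 ± 1.07; 73 and 421), neighbouring paralogs that can share reads, rose with PRX52, a peroxidase (5.14 ± 0.74), and UGT73C1, a glucosyltransferase (4.99 ± 0.60). AT2G27380 (4.79 ± 1.06; 31 and 173 counts in cml39), CML45 (4.72 ± 1.04; 31 and 184) and AT2G16190 (4.64 ± 0.83) followed. Leaving out 1 library moved these sizes. Without wt 1 the fitted values were 5.48 for AT5G24820, 5.10 for AT3G46080, 4.02 for PRX52, 5.59 for UGT73C1, 3.82 for AT2G27380, 3.90 for CML45 and 3.53 for AT2G16190. Without wt 2, which leaves 0 to 2 counts in wt, they were 7.97 for AT5G24820, 7.35 for AT3G46080, 6.98 for AT2G27380 and 6.15 for CML45, while PRX52 and AT2G16190 had limits of at least 28.4-fold and 20.3-fold. Without cml39 1 they were 6.73 for ZAT7, 6.73 for AT3G46080, 5.59 for AT2G27380 and 5.53 for CML45, and without cml39 2 4.42 for ZAT7, 4.07 for AT3G46080, 4.05 for UGT73C1, 2.98 for AT2G27380 and 2.84 for CML45. With limma-voom, ZAT7, AT3G46080, AT2G27380 and CML45 no longer passed (adjusted p = 0.0517, 0.0787, 0.0637 and 0.0689). PI (PISTILLATA), a homeotic gene of petals and stamens, rose from 7.08 ± 1.90 CPM (SD, n = 2) to 167 ± 10.9, by 4.57 ± 0.19 on the log2 scale (adjusted p = 2.58e-05). PAP85, a vicilin-like protein, rose by 4.42 ± 0.29.

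Genes of methionine-derived glucosinolates led the falls. CYP83A1 (876 and 297 counts in wt), IPMI2 (619 and 229) and CYP79F1 (413 and 67) had 0 counts in both cml39 libraries and were at least 314-fold, 227-fold and 128-fold lower. Without wt 1 these limits were 181-fold, 139-fold and 40.8-fold, and without wt 2 that of CYP79F1 was 197-fold. MAM1 fell from 2074 and 775 counts to 1 and 1, a ratio of 1142 with a counting interval of 316 to 9438 (707 without wt 1). TGG2, a myrosinase, changed by -9.71 ± 0.38 on the log2 scale (SE, n = 2; counts of 3665 and 1919 against 4 and 1; -10.89 without cml39 1, -9.12 without cml39 2). AT5G33370 was at least 71.1-fold lower, the paralogs AT4G12520 and AT4G12510, which can share reads, at least 69.8-fold (41.4-fold without wt 1) and 61.5-fold, the cellulase gene CEL5 at least 58.0-fold, the anion channel homologue SLAH1 at least 46.5-fold, MEE3 at least 39.8-fold (118 and 31 counts in wt; 18.9-fold without wt 1) and AT5G33355 at least 35.0-fold. With cml39 1 or cml39 2 left out, 3 counts are taken over 1 library. The limits were then 150 and 163 for CYP83A1, 109 and 118 for IPMI2, 61.5 and 66.9 for CYP79F1, 34.1 and 37.0 for AT5G33370, 33.4 and 36.4 for AT4G12520, 29.5 and 32.0 for AT4G12510, 27.8 and 30.2 for CEL5, 22.3 and 24.2 for SLAH1, 19.1 and 20.8 for MEE3, and 16.8 and 18.24 for AT5G33355. Otherwise each floor is 3 counts over the cml39 group, and floors and intervals cover counting error only.

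Lists of genes fixed in advance were tested against all other genes. Touch and rapid stress response genes formed the list with the largest median rise but for heat shock: 11 of 12 tested members rose and 0 fell, 12 rose adjusted over the list alone, and the median was 2.21 on the log2 scale. TCH4, a xyloglucan endotransglucosylase named for its response to touch, rose from 123 ± 12.8 CPM (SD, n = 2) to 833 ± 44.8 (log2 change 2.76 ± 0.12, adjusted p = 2.65e-05). CML24 (1.63 ± 0.11), ERF6 (2.05 ± 0.20) and ERF1A (1.54 ± 0.17) rose as well. The list was higher than other genes (adjusted p = 4.63e-10; adjusted p = 0.461 with an estimated correlation). Of 9 heat shock genes 6 rose and 1 fell, 7 and 1 adjusted over the list alone, with a median of 2.22 (adjusted p = 7.33e-05; adjusted p = 0.461 with an estimated correlation). The chaperones HSP90.1 (2.22 ± 0.15), HSP101 (1.54 ± 0.16) and HSP23.5 (2.25 ± 0.27) rose, as did HSFA2, a heat stress transcription factor (3.86 ± 0.49).

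Calmodulin and calmodulin-like genes moved both ways. Of 34 tested, 13 rose and 4 fell, also when adjusted over the list alone, with a median of 0.22; CML39 itself was not a member. The list was higher than other genes (adjusted p = 0.0192; adjusted p = 0.461 with an estimated correlation), a call that camera lost on limma-voom values (adjusted p = 0.0853) and without genes that another list holds (adjusted p = 0.0848). After CML38, the lowest p-values were those of CML24 (1.63 ± 0.11), CML16 (1.44 ± 0.23) and CML49 (1.27 ± 0.21). Close relatives among the calmodulin genes can share reads.

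More genes of the circadian clock and of low sugar rose than fell. Of 22 clock genes 14 rose and 4 fell, the same numbers adjusted over the list alone, with a median of 0.84 (adjusted p = 0.00218; adjusted p = 0.461 with an estimated correlation). GI (1.25 ± 0.10), PRR7 (1.26 ± 0.15), ZTL (0.80 ± 0.10) and LUX (1.06 ± 0.14) rose, and ELF4 (-1.49 ± 0.34), GRP7 (-0.81 ± 0.16), PIF4 (-0.60 ± 0.10) and GRP8 (-0.50 ± 0.10), named after their values were seen, fell. The time of day of collection is not in the labels. Of 18 sugar starvation genes 14 rose and 1 fell, also adjusted over the list alone, with a median of 0.72 (adjusted p = 3.35e-06; adjusted p = 0.461 with an estimated correlation). MIOX4, a myo-inositol oxygenase, rose by 3.77 ± 0.15, BCAT2, a branched-chain amino acid transaminase, by 2.51 ± 0.29, DIN4 rose 2.14-fold, while DRM1 fell (-0.95 ± 0.12). Few nuclear photosynthesis genes passed. Of 24 tested, 6 rose and 1 fell, also adjusted over the list alone (median 0.18, adjusted p = 0.260), among them LHCB1.3 (0.86 ± 0.14), RBCS2B (-0.66 ± 0.12), RCA (0.51 ± 0.11) and LHCA4 (0.50 ± 0.13). Members of the LHCB1 and RBCS families can share reads. RCA did not pass without cml39 2 (log2 change 0.47). LHCA4 did not pass without cml39 1 (log2 change 0.44), without cml39 2 (0.54) or with upper quartile scaling (adjusted p = 0.0609). Chloroplast-encoded genes held 0.0348% and 0.0349% of counts in wt and 0.0589% and 0.0506% in cml39. Light stress genes (7 tested) had 4 rises and 1 fall, also adjusted over the list alone, with a median of 0.86 (adjusted p = 0.329; adjusted p = 0.0479 without cml39 1). GPX1 (0.86 ± 0.11) and HYH (1.68 ± 0.30) rose, ZAT12 was 4.30-fold higher (log2 change 1.17 without cml39 2) and CHS fell (-3.59 ± 0.39; -4.34 without cml39 2).

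**Figure D2:**
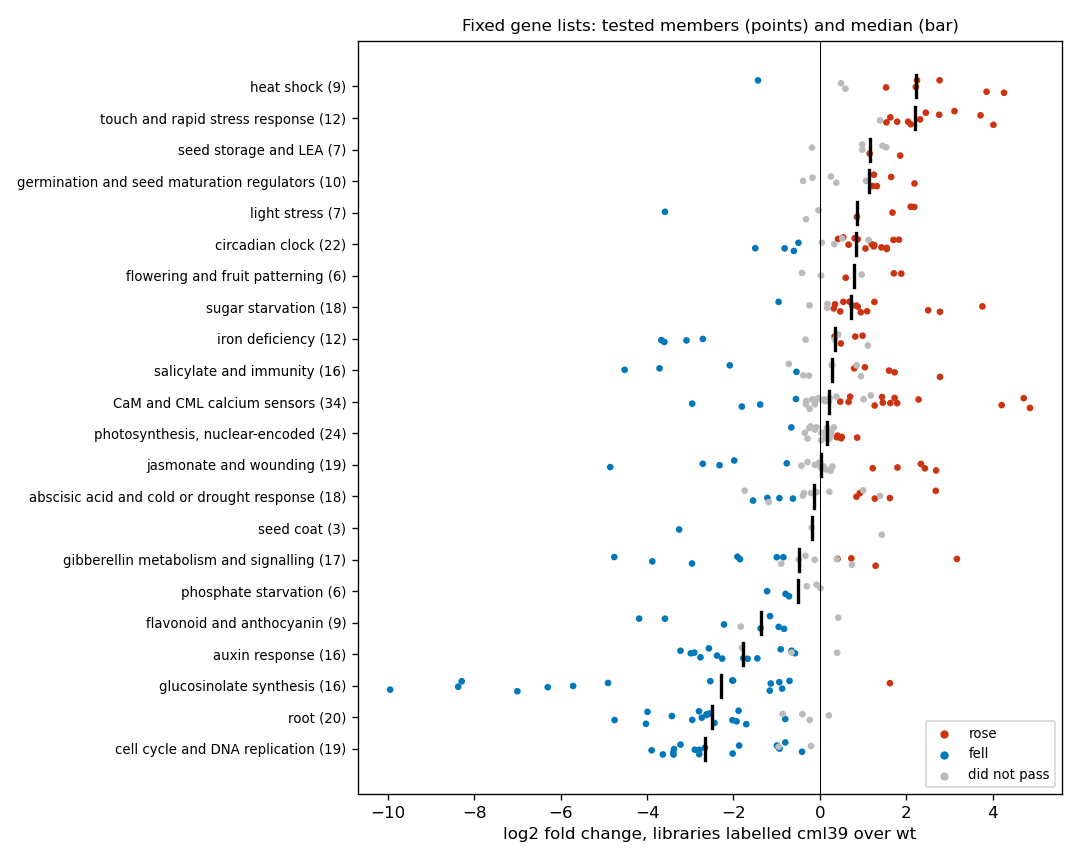
Log2 fold change of every tested member (points; red rose, blue fell, grey did not pass) of the 22 gene lists in the libraries labelled cml39 over wt, with the median of each list as a black bar and genes with 0 counts in a group at their 3-count bound. Medians ran from -2.66 for the cell cycle list to 2.22 for heat shock.

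Transcripts of roots and of dividing cells fell together. Of 20 tested root genes 16 fell and 0 rose, also adjusted over the list alone, with a median of -2.50, or 5.65-fold (adjusted p = 2.10e-08; adjusted p = 0.461 with an estimated correlation). PHO1, which exports phosphate to the xylem (-2.02 ± 0.13), the phosphate transporter gene PHT1;1 (-1.70 ± 0.12) and the aquaporin gene TIP2;3 (-4.75 ± 0.40; -4.06 without cml39 1, -6.02 without cml39 2) fell. PYK10, a myrosinase abundant in roots, fell from 4021 ± 385 CPM (SD, n = 2) to 1091 ± 167 (log2 change -1.88 ± 0.15, adjusted p = 0.000126). Members that did not pass were SCR (0.21), MYB36 (-0.23), PLT2 (-0.86) and PLT1 (-0.40), named after their values were seen. Of 19 cell cycle and DNA replication genes 17 fell and 0 rose, 18 fell adjusted over the list alone, and the median was -2.66 (adjusted p = 5.58e-12; adjusted p = 0.461 with an estimated correlation). KNOLLE, the syntaxin of cytokinesis (-3.39 ± 0.18), the mitotic cyclin genes CYCB1;2 (-3.39 ± 0.22) and CYCB2;4 (-3.23 ± 0.23), and CDKB2;1 (-2.66 ± 0.20) fell. Of 16 auxin response genes 13 fell and 0 rose, also adjusted over the list alone, with a median of -1.79 (adjusted p = 3.35e-06; adjusted p = 0.461 with an estimated correlation). The conjugating enzymes GH3.6 (-2.76 ± 0.20) and GH3.3 (-2.99 ± 0.23) and the repressors IAA29 (-2.38 ± 0.23) and IAA19 (-2.91 ± 0.32) fell, and the SAUR genes of this list can share reads with one another.

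Nutrient lists did not pass as lists. Iron deficiency genes went both ways, 4 up and 4 down of 12 (5 and 4 adjusted over the list alone), with a median of 0.34 but a mean of -0.74 and a test pointing down (adjusted p = 0.0990; adjusted p = 0.0413 without wt 1). The uptake genes IRT1 (-3.67 ± 0.17), FRO2 (-3.60 ± 0.21) and FIT (-3.09 ± 0.22) fell, in the same libraries in which the root list had its median of -2.50, and OPT3, an iron transporter of the phloem, rose by 0.82 ± 0.13. Of 6 phosphate starvation genes 3 fell and 0 rose, also adjusted over the list alone, with a median of -0.51 (adjusted p = 0.340). GDPD1 (-0.71 ± 0.17), PHT1;4 (-0.79 ± 0.22) and MGD2 (-1.22 ± 0.35) fell, and SPX1 had a log2 difference of -0.30 (adjusted p = 0.454). Without wt 1 none of these 3 passed (adjusted p = 0.107, 0.194 and 0.235). PHT1;4 (adjusted p = 0.0566) and MGD2 (adjusted p = 0.0603) did not pass without cml39 1, and MGD2 did not pass without wt 2 (adjusted p = 0.0728) or with DESeq2 (adjusted p = 0.0722). SPX1 passed without cml39 2, at -0.78 (adjusted p = 0.0406), and stood at 0.066 without cml39 1.

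Of 16 glucosinolate synthesis genes 15 fell and 1 rose, also adjusted over the list alone, with a median of -2.28 (adjusted p = 3.70e-07; adjusted p = 0.471 with an estimated correlation). The 9 tested genes of the aliphatic, methionine-derived branch, grouped after the values were seen, all fell, with a median of -6.30 at the 3-count bounds, or 78.8-fold. From summed CPM at the same floor their median fall was 102-fold, and it was 34.7-fold without wt 1, 155-fold without wt 2, 48.8-fold without cml39 1 and 21.4-fold without cml39 2. Their level also differed between the wt libraries, with a median CPM ratio of 3.497 between wt 1 and wt 2, against 1.04 for the root genes. In the authors' deposited table, 1 of the 9 was called lower, MYB28 (log2 change -1.50, adjusted p = 0.0255), and the median of the 9 was -0.11. Fold changes there come from another estimator. They correlated across genes at r = 0.971 with a DESeq2 fit with a prior, which shrinks uncertain changes. The means of the 9 genes in the authors' deposited table were a median of 4.36 times those of the 4 libraries. Whether the prior or the other libraries of the authors' fit gave the median of -0.11 was not tested. That median alone does not show that these genes were unchanged, since all 9 fell in the 4 libraries. Of 5 tested genes of the indolic branch 4 fell and 1 rose, with a median of -1.14. CYP79B3 (-2.54 ± 0.20) and CYP83B1 (-1.14 ± 0.11) fell, while the regulator MYB51 rose by 1.62 ± 0.16. CYP79F1 and its neighbouring paralog can share reads. Flavonoid and anthocyanin genes, with 9 tested, had 7 falls and 0 rises, also adjusted over the list alone, and a median of -1.37 (adjusted p = 0.00594; adjusted p = 0.533 with an estimated correlation). CHS, chalcone synthase (-3.59 ± 0.39; -4.34 without cml39 2), PAL1 (-1.15 ± 0.12) and CHI (-0.83 ± 0.20; adjusted p = 0.130 without wt 1) fell, and the flavonol regulator MYB12 was 19.5-fold lower (counting interval 6.42 to 96.8).

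**Figure D3:**
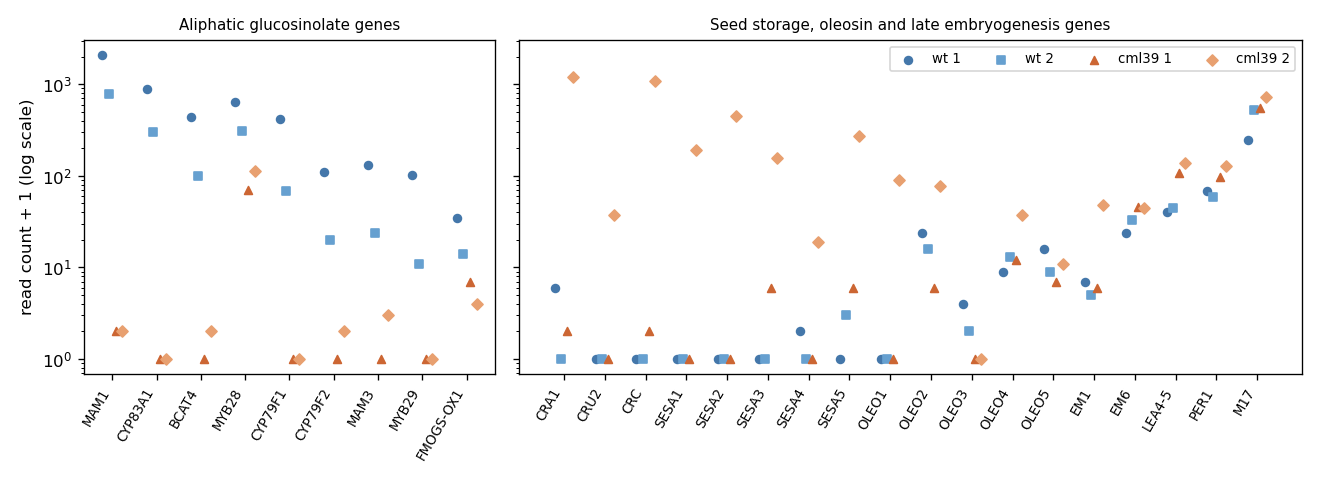
Read count plus 1, on a log axis, of the 9 aliphatic glucosinolate genes and of the 18 seed storage, oleosin and late embryogenesis genes in each library, with 1 point per gene and library. Glucosinolate counts lay lower in both cml39 libraries, while most seed storage counts stood out in cml39 2, where 10 of these genes summed to 3604 counts against 34, 21 and 22 in wt 1, wt 2 and cml39 1.

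Of 10 tested regulators of germination and seed maturation 5 rose and 0 fell, also adjusted over the list alone, with a median of 1.15. The list was higher than other genes in camera (adjusted p = 0.0205, and adjusted p = 0.461 with an estimated correlation). SOM, a repressor of light-dependent germination, rose by 2.19 ± 0.26, the dormancy gene DOG1 by 1.22 ± 0.23, and the abscisic acid hydroxylase genes CYP707A1 by 1.32 ± 0.20 and CYP707A2 by 1.65 ± 0.36. The call was lost without cml39 2 (adjusted p = 0.0562) and when every gene with a count was tested (16 members, adjusted p = 0.0768, median 0.32, or 0.39 for the 13 with over 3 counts in a group at the 3-count bounds), and CYP707A2 did not pass without wt 2 (adjusted p = 0.0501). In cml39 2, 10 of 18 seed storage, oleosin and late embryogenesis genes were over 10 times higher than in cml39 1. Of the 7 genes of that list with enough counts to be tested 2 rose and 0 fell, also adjusted over the list alone, with a median of 1.15 (adjusted p = 0.112). LEA4-5 (1.86 ± 0.31) and PER1 (1.16 ± 0.28) rose, and EM6 (0.98, adjusted p = 0.0848) and M17 (0.98, adjusted p = 0.0881) did not pass. PER1 did not pass without wt 1 (adjusted p = 0.0875) or without wt 2 (adjusted p = 0.0540), and M17 passed without wt 2 (1.86, adjusted p = 0.00155), without cml39 1 (1.24, adjusted p = 0.0174), with limma-voom (adjusted p = 0.0449) and when every gene with a count was tested (adjusted p = 0.0111). The list passed without wt 2 (adjusted p = 0.0336), without cml39 1 (adjusted p = 0.0128) and when every gene with a count was tested (adjusted p = 0.0144). In that last setting the median of its 18 members was 3.45, or a 9.85-fold rise at the 3-count bounds, with the counts of cml39 2 described above. Of 3 seed coat genes 1 fell and 0 rose, 1 and 1 adjusted over the list alone, with a median of -0.19 (adjusted p = 0.661; median -1.19 when every gene with a count was tested, 3 of 6 then having at most 3 counts in each group). TTG2 fell (-3.26 ± 0.55; -4.72 without cml39 1, -2.58 without cml39 2), and TT10 (1.44, adjusted p = 0.0534; adjusted p = 0.0154 without cml39 1) and AHA10 (-0.19, adjusted p = 0.821) did not pass.

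The gibberellin, abscisic acid, jasmonate and salicylate lists each held rises and falls. Of 17 gibberellin genes 4 rose and 7 fell, 4 and 8 adjusted over the list alone, with a median of -0.49 (adjusted p = 0.329). GASA6 (-2.96 ± 0.14) and GASA4 (-1.91 ± 0.15) fell, while GASA1 rose by 3.17 ± 0.17 and the receptor gene GID1A by 1.29 ± 0.12. Of 18 abscisic acid and cold or drought genes 5 rose and 4 fell, 5 and 5 adjusted over the list alone, with a median of -0.14 but a mean of 0.09 and a test pointing down (adjusted p = 0.987). RD22 (-1.54 ± 0.10) and LTI30 (-0.94 ± 0.16) fell and the phosphatase gene ABI1 (0.93 ± 0.12) and ADH1 (1.62 ± 0.25) rose. Jasmonate and wounding genes, 19 tested, had 5 rises and 5 falls, also adjusted over the list alone, with a median of 0.017, a mean of -0.12 and a test pointing down (adjusted p = 0.865); upper quartile scaling put the median at -0.13. AOS (-1.98 ± 0.13) and LOX2 (-2.32 ± 0.29) of jasmonate synthesis and the storage protein gene VSP1 (-4.85 ± 0.62; -7.57 without cml39 1, -4.02 without cml39 2) fell, and LOX4 rose by 2.43 ± 0.29. Salicylate and immunity genes, 16 tested, had 5 rises and 4 falls, also adjusted over the list alone, with a median of 0.28 but a mean of -0.35 and a test pointing up (adjusted p = 0.661). WRKY33 (1.60 ± 0.24) and FRK1 (2.78 ± 0.45; 2.16 without wt 1, 3.75 without wt 2) rose, EDS5 fell (-2.08 ± 0.36) and PR5 was 24.6-fold lower (counting interval 8.16 to 121; at least 11.8-fold without cml39 1, 12.8-fold without cml39 2). Flowering and fruit patterning genes had 3 rises and 0 falls of 6, also adjusted over the list alone, with a median of 0.78 (adjusted p = 0.0990; median 0.029 over 9 members when every gene with a count was tested, or 0.32 at the 3-count bounds for the 8 with over 3 counts in a group). The repressor of flowering FLC rose by 1.71 ± 0.16, SOC1 by 0.60 ± 0.14 and MAF5 by 1.89 ± 0.60 (1.25 without wt 1, 2.82 without wt 2), and MAF4 did not pass (0.97, adjusted p = 0.0954; 1.41, adjusted p = 0.00742 without cml39 1, and 0.36 without cml39 2). SOC1 (adjusted p = 0.120) and MAF5 (adjusted p = 0.276) did not pass without wt 1, nor did MAF5 without cml39 2 (adjusted p = 0.0636), with DESeq2 (adjusted p = 0.0766) or with upper quartile scaling (adjusted p = 0.0515).

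Of the 22 lists, 11 passed with a preset correlation between genes, 6 higher and 5 lower. With the correlation estimated from these libraries 0 passed in camera, and 0 lists had an unadjusted p under 0.05. That setting tests on the few residual degrees of freedom of 4 libraries, so its failures do not show that correlation undoes a list. For the calmodulin and calmodulin-like list the estimated correlation was 0.0127, near the preset 0.01. Its unadjusted camera p was 0.00871 with the preset and 0.126 with the estimate. Other lists that passed had higher estimates: 0.728 for glucosinolate synthesis, 0.708 for cell cycle, 0.602 for touch, 0.489 for flavonoid and 0.376 for sugar starvation genes. Root had 0.0677, and auxin, germination, clock and heat shock had 0.101 to 0.162. Where an estimate lies far above the preset and holds, the p-value with the preset is too small. By how much was not tested. In limma's fry, whose directional test asks whether a list's genes move one way on balance, 0 passed (smallest adjusted p = 0.0569) and 12 had an unadjusted p under 0.05. Its mixed test, for change in either direction, gave adjusted p from 0.00874 (root among others) to 0.0926 (seed storage). Neither fry test compares a list with other genes.

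Changed genes were not detectably more frequent around CML39. Within 1 Mb, 205 of 462 tested genes changed (44.4%), against 7871 of 19301 elsewhere (40.8%). The odds ratio was 1.16 (95% interval 0.957 to 1.40; Fisher's exact test, two-sided, p = 0.125). It was 1.25 without wt 1 (Fisher's exact p = 0.0433), 1.21 without cml39 2 (Fisher's exact p = 0.0453) and 1.25 when every gene with a count was tested (Fisher's exact p = 0.0129). Neighbouring genes are not independent.

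The authors' deposited table called 3312 of 20717 genes with an adjusted p, 1497 higher and 1815 lower. All 3312 passed here in the same direction, 4795 genes passed here alone and 0 in the authors' deposited table alone. The authors' deposited table rests on more libraries than these 4, which are not analysed here: 349 of its 23971 genes have a mean above 0 and no count in any of the 4, and 22047 of its means (92.0%) lie over 1% off the mean of the 4 libraries. The log2 fold change was 0 in the authors' deposited table for all 349, so the libraries that hold their counts lie outside its cml39 and wt groups. A gene it did not call is therefore not shown to be unchanged in other libraries, and agreement with it is not independent support. DESeq2 with a prior on fold changes called 6755 genes on the 4 libraries, with a median standard error of 0.239 against 0.323 in the authors' deposited table. Across genes, which are not independent replicates, the log2 values of the authors' deposited table correlated at r = 0.971 with those of that fit (slope 0.805) and at 0.898 with the fit here, so that its values and those here come from different estimators. PI (3.40, adjusted p = 1.77e-08) and CML38 (4.38, adjusted p = 1.24e-30) were called higher in the authors' deposited table. Genes that passed here alone, by lowest p, were BGLU18 (-6.06 ± 0.23 here), TGG2 (-9.71 ± 0.38; -10.89 without cml39 1, -9.12 without cml39 2), ECS1 (-3.83 ± 0.16), GASA6 (-2.96 ± 0.14) and IRT1 (-3.67 ± 0.17), with -1.47, -0.76, -1.51, -1.42 and -1.06 in the authors' deposited table. By list, the calls of the authors' deposited table held 11 rises of touch genes, 6 of heat shock genes, 4 each of sugar starvation and light stress genes and 1 of the flowering list, with 0 falls in these. It held falls of 10 cell cycle, 9 root, 5 auxin, 1 flavonoid and 1 seed coat genes, with 0 rises. In both directions the authors' deposited table called calmodulin and calmodulin-like (10 up, 2 down), clock (4, 1), glucosinolate (1, 2), gibberellin (2, 3), abscisic acid (3, 2), jasmonate (4, 1), salicylate (3, 1) and iron genes (1, 2), and none among germination regulators, seed storage, photosynthesis or phosphate genes.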

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

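The count in this part, and its comparison with the authors' means, were chosen after the authors' deposited table had been seen. A mean normalized count above 0 stood in the authors' deposited table for 349 genes that had 0 counts in all 4 libraries, which is a signal from libraries that the comparisons here do not use. In the authors' deposited table their log2 fold change was 0 in all 349, 7 had a mean above 3 and the highest mean was 12.5.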

How the results depend on the processing

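No alternative in this part was chosen after the results were seen. CML39 kept its direction and passed in all of them, with a fitted log2 change, which depends on the prior count, from 6.29 to 8.67. The 8107 genes changed became 6744 to 8718 with another scaling, filter, fit or tool, and 4177 to 8364 with 1 library left out (3822 higher became 1997 to 3943, 4285 lower became 2180 to 4421, and 4105 at least 2-fold became 2719 to 4390), the lowest each time without wt 1. Leaving out a library leaves a group with 1, which is assumed to vary like the other group. Of the 11 lists called, 0 passed with an estimated correlation and 0 by fry, and 10 to 13 passed with 1 library left out. The odds ratio near CML39 was 1.25 when any gene with a count was tested, and 1.09 to 1.25 with 1 library left out. Of 108 named genes besides CML39, 101 passed, 89 kept direction and side of the threshold in all alternatives, and 2 changed direction, neither of which had passed before. AHA10 ranged from -0.70 to 0.22 and SPX1 from -0.78 to 0.066 with 1 library left out. The camera direction of the abscisic acid list turned upward with upper quartile scaling (median -0.28), any gene with a count (-0.070), at least 1 CPM in 2 libraries (-0.15) and the replicate block (-0.13), and without wt 2 or cml39 1, and its median ranged from -0.17 to -0.11 with 1 library left out. That of the jasmonate list turned without cml39 2, with medians from -0.12 to 0.098 with 1 library left out. Neither list passed in any of these, and the cause of these shifts was not tested. Libraries of the same number share only that number: their deviations from the group means correlated at -0.17 over genes, and a replicate block gave 6744 genes, 6705 of them among the 8107; under it RCA (adjusted p = 0.0503), LHCA4 (adjusted p = 0.0621) and MGD2 (adjusted p = 0.0614) did not pass and M17 did (adjusted p = 0.00746). Depth limits low genes, since 3 counts are 0.113 to 0.164 CPM in a library.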

Other observations

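The gene family comparisons and all tests of explanations in this part were chosen after the results were seen. Families in the reference annotation with at least 15 tested genes, 122 in all, were compared with the 18275 annotated tested genes, of which 19.3% rose and 22.2% fell, by Fisher's exact test, two-sided, adjusted over families and directions. Falls were more frequent among lipid-transfer and 2S albumin proteins (36 of 52, adjusted p = 1.39e-10), peroxidases (29 of 45, adjusted p = 1.17e-07), acyl-transferases of the HXXXD type (26 of 41, adjusted p = 4.11e-07) and pectin lyase-like proteins (27 of 47, adjusted p = 3.85e-06). They were also more frequent among ribosomal proteins (103 of 275 fell and 19 rose, adjusted p = 2.70e-07) and histones (16 of 28 fell and 0 rose, adjusted p = 0.000915), which stood beside the fall of the cell cycle list. Their median log2 changes were small, -0.29 for ribosomal proteins and -0.61 for histones, against -2.18 to -0.96 in the families named before them. Disease resistance proteins of the TIR-NBS-LRR class rose more often (24 of 52, adjusted p = 0.000182), RPP4 by 1.68 ± 0.14 and RPP5 by 1.12 ± 0.11 on the log2 scale (SE, n = 2). Pentatricopeptide repeat proteins changed less often both ways (11 of 178 fell, adjusted p = 2.92e-07, and 8 rose, adjusted p = 3.97e-07). Members of these families can share reads and are not independent. With DESeq2 size factors and with upper quartile scaling, the comparisons with a p-value here kept their direction and passed (adjusted p from 1.40e-12 to 0.00332). The families named here are some of those that passed. Over all that passed, 57 comparisons under these scalings stayed the same and 13 no longer passed. Falls of RING/U-box proteins, for example, did not pass with upper quartile scaling (Fisher's exact test, adjusted p = 0.0591).

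While PI rose, the other floral organ genes looked at had few counts or did not pass. AP1 and SEP2 had 0 counts in all 4 libraries, AP3 had 2 and 1 counts in wt and 0 in both cml39 libraries, AG had 4, 1, 0 and 1 and SEP1 2, 0, 0 and 1 in wt 1, wt 2, cml39 1 and cml39 2. SEP3 had a log2 difference of 0.18 ± 0.24 (adjusted p = 0.584). These genes were chosen after the rise of PI was seen.

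The first pattern weighed is the CML39 reads in the libraries labelled cml39. Those libraries held 2.24 CML39 counts per 100 counts of CML38, upstream on the same strand (4.12 in cml39 1 and 1.14 in cml39 2); if reads running on from CML38 gave that ratio, wt would hold 2.85 CML39 counts, and its 0 counts had a Poisson probability of 0.0578. This rests on the library taken, since at the ratio of cml39 1 alone wt would hold 5.23 counts (probability 0.00536) and at that of cml39 2 alone 1.44 (0.236). A single ratio did not hold between the cml39 libraries. CML39 had more counts where CML38 had fewer, 45 with 1093 in cml39 1 and 21 with 1848 in cml39 2. These probabilities, which assume such a ratio, therefore do not decide on reads running on, which is left open. Labels of the groups exchanged may also explain the 0 CML39 counts in both wt libraries, and no other gene here marks the genotype. Both cannot be told apart from an effect of the genotype, since each divides the libraries the same way, and the genotype itself, such as a transcript of the altered gene, was not tested.

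The second is the fall of root and aliphatic glucosinolate genes. Less root in those samples may lower the root genes, of which 16 of 20 fell and 0 rose, but 10 of 20 lay more than 2 standard errors from the median of the list, further apart than an even loss would put them, and how much of each is expressed in the shoot was not measured, so this cannot be told apart from other changes. For the aliphatic genes, 7 of 9 fell by more than the root genes with a count in both groups (TIP2;3 the most, at -4.75). In summed CPM with 1 library left out, 4 to 7 did so. WOX5, at 0 counts in cml39 and at least 6.95-fold lower, cannot be ranked. Its limit was 3.33-fold without cml39 1 and 3.62-fold without cml39 2. The median fall of the aliphatic genes, 78.8-fold at the 3-count bounds, exceeded the 5.65-fold of the root genes. Their level also differed between wt 1 and wt 2 (median CPM ratio 3.497), where that of the root genes hardly did (1.04). These values argue against less root as the only cause for the aliphatic genes as a set. Shoot expression of the root genes, which was not measured, could still hide a larger loss, so a part played by less root is not excluded. A state of the 4 libraries that other libraries do not share was not decided for the aliphatic genes: 1 of the 9 was called lower in the authors' deposited table, but its log2 fold change was 0 for all 349 genes without a count in the 4 libraries, so a missing call there says nothing of other libraries, and its means, at a median of 4.36 times those of the 4 libraries (1.03 for root genes), show more of these transcripts in libraries whose group is not known here. An effect of the genotype or of the growth of the plants stays open and was not tested.

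The third is the seed storage transcripts of cml39 2. Reads carried over from a seed-rich library behind the authors' deposited table are argued against only if its fit held few libraries. The means of the 10 genes there were a median of 0.684 times those of the 4 libraries. How many libraries that fit held is not known, and a mean over many could hide a seed-rich library, so carry-over is not excluded. The 13 storage protein and oleosin genes summed to 3621 counts in cml39 2, 34 in cml39 1 and 55 and 38 in wt. In cml39 1 they stood at 0.875 times the wt level (counting interval 0.573 to 1.31), so the rise of cml39 2 was not shared by cml39 1. A smaller rise by the genotype in both libraries is left open. Most of these genes had too few counts to tell, and PAP85, outside the list, rose in both (26 and 31 counts in wt, 416 and 568 in cml39). Seed material in that sample may explain the 10 genes, which were over 10 times higher there than in cml39 1, among them 9 of 13 storage protein and oleosin genes (CRA1 had 1213 counts and CRC 1080), but 1 of 5 late embryogenesis genes was among them, so this stays undecided. Over all genes, 16 with at least 30 counts were over 10 times higher in cml39 2 than in every other library, 9 of them in the seed list, and 0 genes were so in each of the other libraries. LEC1, LEC2 and FUS3, regulators of embryos, together had 5, 3, 0 and 1 counts in wt 1, wt 2, cml39 1 and cml39 2.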
